A study of Homo sapiens with 2 samples.

How the data were processed

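RNA sequencing libraries of 2 cultures of MCF7L, a line of the estrogen receptor-positive human breast cancer line MCF-7, were compared. MCF7L-P is labelled tamoxifen-sensitive and MCF7L-TamR tamoxifen-resistant, with 1 library each. Per the labels' protocols, P cells grew in RPMI medium with 10% heat-inactivated fetal bovine serum and 1% penicillin, streptomycin and glutamine. TamR cells were kept without phenol red, in 10% charcoal-stripped serum with the same supplement at 1% and 100 nM 4HT, as the labels name the drug. The labels therefore tie resistance, medium and drug together, and these cannot be told apart. Total RNA was extracted with an RNeasy Mini kit and libraries were made with the TruSeq RNA sample preparation kit, per the labels' protocols. BWA 0.5.8a and the genome build hg19 are named in the submitters' processing notes, with no role given. The program that estimated expression, its treatment of reads shared between genes and its use of strand are not given in the sources used here.

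The authors deposited FPKM values (fragments per kilobase of transcript, scaled to the mapped fragments of the library) for 77607 transcripts, identified by UCSC known gene IDs paired with gene symbols in the table. Tiny values above 0 were frequent: 4.40% of P values and 4.36% of TamR values lay above 0 and under 0.001 FPKM. The table gives neither transcript lengths nor counts, and whole reads were not recovered from it. The depth of both libraries is unknown, and no counting interval or detection limit could be given. FPKM is relative to each library's total, and a few abundant genes can lower all others. The 10 most abundant genes held 9.74% of the P total and 9.02% of the TamR total.

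The authors also deposited a comparison table of 615 transcripts with an FPKM value for each culture, a log2 ratio and a q-value. Tested on the file, every q-value was under 0.05, and every log2 ratio was that of FPKM + 1 to within rounding. Without the added 1 the smallest log2 ratio was 2.01 in size. The method behind the q-values is not given in the sources used here. None of the 615 pairs of FPKM values equalled those of the same transcripts in the FPKM table. Whether the comparison table came from another quantification or another scaling is not given in the sources used here. Its values are given only as the authors'. Its loci are given as deposited on hg19, and whether their starts count from 0 or 1 is not stated.

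FPKM values were summed over the transcripts of each symbol, which gave 29234 symbols, of which 13637 had 1 transcript. The log2 ratio was log2((TamR + 1) / (P + 1)), with a pseudocount of 1 FPKM, which understates the ratios of genes at low levels. Folds are on the same scale. Genes at 1 FPKM or more in at least 1 library were kept (13248 genes). With 1 library per group there was no test, standard error or p-value, and genes were counted as higher or lower at 2-fold. The plan written before the data were examined foresaw this case and was followed. An exact 0 can be a failed estimate in such tables. It occurred in 1 library for 52 of the kept genes and for 0 of 14 common reference genes.

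28 gene lists were fixed before the data were examined. For lists with at least 5 kept members, the median log2 ratio was placed among the medians of 10000 random lists of the same size, drawn from 20 bins of mean log2 expression. A percentile under 2.5 or over 97.5 was taken to stand apart. It describes these 2 libraries, not the conditions. List symbols were matched to older symbols in the tables through the synonyms of the RefSeq gene table (GRCh38.p14), of which no coordinate is given. 17179 of the symbols were current and 2700 were synonyms of 1 current gene. The same table gave the order along chromosomes of 11273 of the kept genes (85.1%). Medians over windows of 41 neighbouring genes, chosen after the data were seen, were compared with those of 100 shuffled gene orders.

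Genes named in the text were chosen by a rule written before the data were examined. It takes the 12 highest and 12 lowest log2 ratios among genes at 5 FPKM or more in one library with a gene symbol, leaving out small RNAs and LOC and LINC names. It adds ESR1, PGR, FOXA1, GATA3, ERBB2, EGFR and IL8 (CXCL8), and up to 4 members of each list with the largest log2 ratio in either direction. In the authors' deposited table it takes the 5 smallest q-values per direction, with ties broken by the larger log2 ratio. The written rule also left out symbols in more than 1 row. This was not applied to transcripts, which were summed per symbol. A gene symbol was taken to be a current symbol, or a synonym of exactly 1 gene that is not itself in the table. The written rule did not hold that definition. 8416 of the 9058 genes at 5 FPKM or more were eligible. Members named outside this rule were chosen after their values were seen and are marked as such. Some loci shared by near-identical copies, and a transcript antisense to another gene, are given as uncertain. No systematic search for such copies was made, so other named genes may be affected.

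The calculation was tested on simulated data for 12390 genes around the mean level of both libraries, with a noise of 0.2 on the log2 scale and 200 changed genes. That noise was assumed, since no replicates exist, and the changed genes were drawn from those at a mean level of 5 FPKM or more. All genes made 4-fold higher, 4-fold lower or 3-fold higher passed 2-fold, as did 0% of the unchanged genes. These figures check the calculation and give no error rate for 2-fold calls in these libraries. Of 100 lists of 15 unchanged genes, 8% lay outside the 2.5 and 97.5 percentiles. The alternatives set before the data were examined were pseudocounts of 0.1 and 5 FPKM, no filter, a filter at 5 FPKM, median-centred ratios, equal totals, upper-quartile scaling and fold thresholds of 1.5 and 4. The plans for several columns per cell line did not apply, as each had 1. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.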

Results

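Gene expression was measured by RNA sequencing in tamoxifen-sensitive MCF7L-P cells and tamoxifen-resistant MCF7L-TamR cells, with 1 library each. MCF7L is a line of MCF-7, an estrogen receptor-positive breast cancer line. Tamoxifen blocks estrogen signalling through that receptor. The comparison asked how resistant cells differ in expression from the sensitive cells of the same line. There were no replicates, so no difference has a replicate check. The cultures also differed in medium, since TamR cells were kept in charcoal-stripped serum with 100 nM 4HT. Sequencing depth is unknown. FPKM summed to 490049 in P and 474987 in TamR, and 12409 and 12247 genes reached 1 FPKM.

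The genes with the largest log2 ratios included matrix genes and the chemokine gene IL8 on the higher side and estrogen-induced genes on the lower side. FN1, which encodes the matrix protein fibronectin, went from 1.95 FPKM in P to 756 FPKM in TamR, the highest log2 ratio of the eligible genes (8.01). LDHB, a subunit of lactate dehydrogenase, stood at 0.39 and 156 FPKM (log2 ratio 6.82). IL8, the chemokine gene now named CXCL8, stood at 0.12 and 114 FPKM (6.68). The calcium-binding protein gene S100P reached 1882 FPKM from 19.6 FPKM (6.51), and BMP7, a bone morphogenetic protein gene, 891 FPKM from 22.9 FPKM (5.22). TPM2, a tropomyosin gene (6.49), EPAS1, which encodes the hypoxia-inducible factor HIF-2α (5.92), and COL3A1, a fibrillar collagen gene (5.82), were also among the 12 highest. The others were GBX2 (5.35), MUCL1 (4.91), the Notch target HEY1 (4.73) and KRT81 (5.66). KRT81 has near-identical hair keratin copies, so its own value is uncertain.

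At the other end, SUSD3, an estrogen-induced gene, stood at 118 FPKM in P and 0.33 FPKM in TamR, the lowest log2 ratio of the eligible genes (−6.48). The carbonic anhydrase gene CA12 (−6.18) and GREB1, a coregulator of the estrogen receptor (−6.02), followed. HSPB8, a small heat shock protein gene, was at 125 and 0.98 FPKM (−5.99), and RAB34 at 68.8 and 0.27 FPKM (−5.79). GSTM3 (−5.56), MAPK13 (−5.54), EFHD1 (−5.47), the cytokine gene IL20 (−5.46) and IFI30 (−5.41) were each over 40 FPKM in P and under 3 FPKM in TamR. M41, now named DSCAM-AS1, stood at 341 and 5.87 FPKM (−5.64). It is antisense to another gene and strand use is not stated. SPANXA1 (−6.02) belongs to a family of near-identical copies. Both values are therefore uncertain.

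Of 13248 genes at 1 FPKM or more in one library, 1152 (8.70%) were at least 2-fold higher in TamR and 1248 (9.42%) at least 2-fold lower. At 4-fold the counts were 308 and 263, and at 8-fold 112 and 96. Across genes, which are not independent replicates, log2 FPKM correlated between the libraries with a Pearson r of 0.884 and a Spearman rho of 0.866. The median log2 ratio was −0.13 over these genes and −0.09 over the 7320 genes at 5 FPKM or more in both. With a pseudocount of 5 FPKM the counts at 2-fold were 530 and 474, and 16 genes named below came within 2-fold. These were ERBB2, TGFB3, TP53INP1, NRIP1, LIF, VIM, PSMB9, CYP51A1, PLIN2, ANGPTL4, CA9, ABCC1, SOX9, XIAP, TP53I3 and FKBP5.

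**Figure D1:**
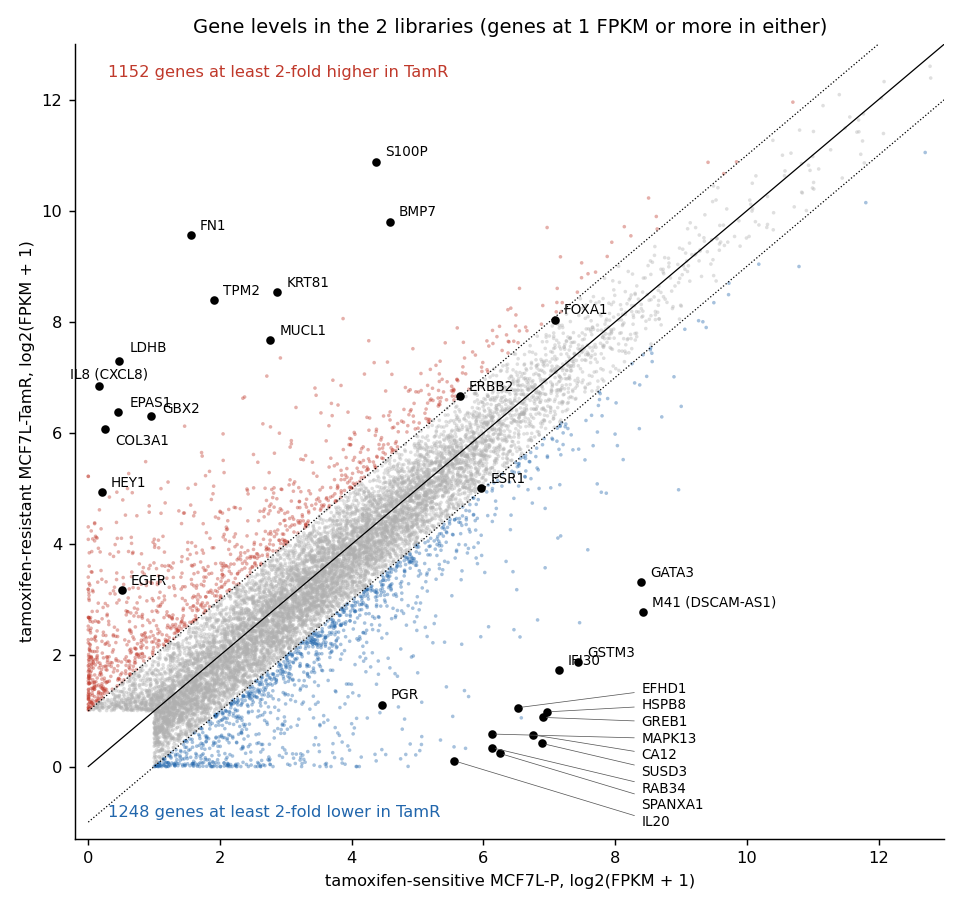
Each point is a gene at 1 FPKM or more in either library, with log2(FPKM + 1) in P on the horizontal axis and in TamR on the vertical axis; the solid line marks equal levels and the dotted lines 2-fold. Red points are the 1152 genes at least 2-fold higher in TamR and blue points the 1248 at least 2-fold lower, with FN1, S100P and BMP7 far above the line and GATA3, GREB1 and SUSD3 far below it.

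Genes known to be induced by estrogen were mostly lower in TamR. These cells were kept in charcoal-stripped serum with 4HT and without phenol red, so resistance, medium and drug cannot be told apart here. Of 29 measured estrogen-induced genes, 17 were at least 2-fold lower and 3 at least 2-fold higher. Their median log2 ratio was −1.08, at percentile 0 of 10000 random lists matched on expression. Besides SUSD3, CA12 and GREB1, the scaffold gene PDZK1 went from 46.0 to 0.28 FPKM (−5.20). PGR, the progesterone receptor gene, went from 21.0 to 1.16 FPKM (−3.35). AREG, the EGFR ligand amphiregulin, and the trefoil factor gene TFF3 were higher, with log2 ratios of 2.20 and 2.73. TFF1, MYC and CCND1, named after their values were seen, were within 2-fold, at −0.40, 0.0013 and 0.25. Genes known to be repressed by estrogen went the other way. Of 10 measured, 4 were at least 2-fold higher and 0 lower, and their median was 0.79 (percentile 99.96). These 4 were BCAS1 (3.22), TGFB3 (1.19), TP53INP1 (1.03) and ERBB2 (1.02). With a pseudocount of 5 FPKM, TGFB3 (0.85), TP53INP1 (0.61) and ERBB2 (0.97) were within 2-fold.

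The receptor itself was still expressed. ESR1, which encodes estrogen receptor α, stood at 61.5 FPKM in P and 31.3 FPKM in TamR (−0.95, 1.94-fold lower). By its most abundant transcript alone, a setting added after the data were seen, ESR1 was past 2-fold lower (−1.25). FOXA1, a pioneer factor that opens chromatin for the receptor, was 1.94-fold higher, at 134 and 262 FPKM (0.96). It passed 2-fold under each of 3 other scalings, with log2 ratios of 1.05, 1.01 and 1.04. The 20 expressed genes nearest to FOXA1 had a median log2 ratio 0.91 above that of all genes. GATA3, a luminal transcription factor that acts with both, went from 336 to 8.98 FPKM (−5.08). The list of 18 steroid receptors, pioneer factors and coregulators had 5 genes at least 2-fold lower and 0 higher, but its median of −0.26 lay at percentile 15.7. GPER, a membrane estrogen receptor gene (−2.63), and the corepressor gene NRIP1 (−1.56) were among the lower ones.

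Markers of epithelial lineage moved in both directions. Of 15 luminal markers, 4 were at least 2-fold lower and 2 higher, with a median of −0.06 (percentile 45.1). The mucin gene MUC1 was lower (−1.74), and AGR2, a disulfide isomerase of secretory cells, went from 6.55 to 162 FPKM (4.43). Of 15 basal and myoepithelial markers, 7 were measured, with 3 higher and 0 lower. The higher ones were EGFR, from 0.42 to 8.03 FPKM (2.67), the laminin gene LAMC2 (2.60) and the integrin gene ITGB4 (1.24), while KRT17 was at −0.64. The unmeasured ones, named after their values were seen, were KRT5, KRT6A, KRT6B, KRT14, TP63, MYLK, CNN1 and CAV1. All of them were under 1 FPKM in both libraries. The basal median of 0.55 lay at percentile 95.8, and at 98.4 with a pseudocount of 0.1 FPKM. Among 5 measured mesenchymal markers, FN1, SERPINE1 (1.77) and VIM (1.08) were higher and S100A4 lower (−2.33). Their median was 1.08 (percentile 99.5). VIM reached only 3.77 FPKM, and without the filter on low values the mesenchymal median was −0.0075 (percentile 35.7).

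Genes that respond to serum and growth factors had the highest median of the lists with at least 5 measured members. Of 21 immediate early and ERK feedback genes, 15 were at least 2-fold higher in TamR and 1 lower, with a median of 1.99 (percentile 100). EGR3 was the lower one (−1.47), and JUN (−0.03), DUSP1 (0.46) and IER3 (−0.42) were within 2-fold, all named after their values were seen. DUSP6, a phosphatase that inactivates ERK, went from 0.53 to 37.6 FPKM (4.66), and SPRY4, a feedback inhibitor of receptor tyrosine kinases, from 0.59 to 29.4 FPKM (4.26). The transcription factor gene EGR1 stood at 13.6 and 266 FPKM (4.19), and CTGF, now named CCN2, at 0.097 and 16.3 FPKM (3.98). The 17 measured genes of the list of ERBB, IGF and FGF receptors and ligands were mixed, with 5 higher and 3 lower. The lower ones included IRS1 (−1.32) and IRS2 (−1.26), which encode adaptors and not receptors or ligands. The receptor gene FGFR3 was higher (2.20), and these 3 were named after their values were seen. BTC, the EGFR ligand betacellulin, was higher (2.70) and FGFR4 lower (−3.56). Their median was −0.02 (percentile 68.8) although their mean was 0.23, and with a filter at 5 FPKM the median was 0.49 (percentile 98.8).

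Few inflammatory cytokine genes were expressed. Only 4 of 20 reached 1 FPKM in a library: IL8, CXCL12, LIF and NFKBIA. CXCL12, an estrogen-induced chemokine gene, went from 25.8 to 0.10 FPKM (−4.60). LIF, a cytokine of the IL-6 family, was higher (1.53), and NFKBIA, an NF-κB target that encodes its inhibitor, was within 2-fold (0.09). Interferon-stimulated genes were lower. Of 25 listed, 14 were measured, with 10 at least 2-fold lower, 0 higher and a median of −2.11 (percentile 0). The other 4 measured were STAT2 (0.56), OAS1 (0.47), STAT1 (0.12) and DDX58 (−0.39), named after their values were seen. The antiviral genes BST2 (−3.95), IFITM1 (−3.62) and IFITM3 (−2.52) and the transcription factor gene IRF7 (−2.94) had the lowest ratios. IFITM3 alone went from 512 to 88.3 FPKM. The IFITM genes are close copies, so their values are uncertain. IFITM1 and IRF7 lie near each other on chromosome 11 in the authors' deposited table, and the percentile takes no account of this. Antigen presentation genes were split. Of 11 measured, 5 were at least 2-fold lower and 0 higher: the peptide transporter genes TAP1 (−1.90) and TAP2 (−1.51), the immunoproteasome gene PSMB9 (−1.53), B2M (−1.32) and, named after its value was seen, TAPBP (−1.13). The list's median was 0.24 (percentile 90.9) and its mean −0.32, so these differed in sign. HLA-A (0.66), HLA-B (0.79), HLA-C (0.88), HLA-E (0.53) and HLA-F (0.73), also named after their values were seen, were within 2-fold. HLA genes have near-identical copies, and these genes, TAP1, TAP2, TAPBP and PSMB9 lie in a region with several haplotypes in the annotation, so their values are uncertain.

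Proliferation genes were lower on balance. Of 28, 7 were at least 2-fold lower and 0 higher, with a median of −0.77 (percentile 0). E2F1, which drives entry into S phase, went from 32.0 to 6.69 FPKM (−2.10). MCM7 and MCM3 of the replicative helicase were at −1.88 and −1.49, and TK1, a thymidine kinase of S phase, was at −1.66. The other 21 genes of the list were within 2-fold, and 5 of these lay above 0. They were the mitotic genes AURKA (0.31), UBE2C (0.27), CCNB1 (0.25) and PLK1 (0.08), and RRM2 (0.09), all named after their values were seen. Among 15 p53 targets, 5 were higher and 1 lower, with a median of 0.69 (percentile 99.96). CDKN1A, the cell-cycle inhibitor p21, went from 74.8 to 241 FPKM (1.68), and GDF15 was at 1.90, whereas TP53I3 was lower (−1.43). Of 14 apoptosis regulators, 2 were higher and 2 lower. BCL2, a survival gene induced by estrogen in breast cancer cells, went from 19.4 to 0.16 FPKM (−4.13), and XIAP was also lower (−1.10). The survival gene MCL1 (1.23) and the pro-apoptotic gene BID (1.69) were higher. The apoptosis median of 0.27 lay at percentile 96.9, with a mean of −0.01.

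Stress and metabolic genes were higher on balance. Of 14 genes of the unfolded protein response, 6 were at least 2-fold higher and 1 lower, with a median of 0.74 (percentile 99.99). DDIT3 (CHOP) went from 19.5 to 61.2 FPKM (1.60), and HERPUD1 (1.52), SESN2 (1.33) and CHAC1 (1.32) were also higher. Of 17 hypoxia and glycolysis genes, 6 were higher and 0 lower, with a median of 0.65 (percentile 99.95). The hydroxylase gene EGLN3 (1.80), NDRG1 (1.65) and the carbonic anhydrase gene CA9 (1.43) were among them, and ANGPTL4 went from 1.05 to 4.79 FPKM. EGLN3 lies in the same run of higher genes as FOXA1. Of 16 genes of fatty acid synthesis and lipid storage, 5 were higher and 2 lower, with a median of 0.47 (percentile 99.8). The acyl-CoA synthetase genes ACSL1 (2.59) and ACSL3 (2.02) were higher, and the elongase gene ELOVL5 (−2.30) and the lipid droplet gene PLIN2 (−2.27) lower. Of 17 cholesterol genes, 2 were higher and 1 lower, with a median of 0.31 (percentile 98.5). LSS (1.57) and DHCR24 (1.28) were higher, CYP51A1 was lower (−1.21), and the receptor gene LDLR was at 0.96. Of 16 genes of tamoxifen metabolism and drug transport, 4 were measured. CYP1B1, an estrogen hydroxylase, went from 1.29 to 9.47 FPKM (2.20), and ABCC1 (1.01), UGT2B15 (0.99) and SULT1A1 (0.94) were about 2-fold higher.

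Adhesion genes, Notch genes and the measured stem-like and ALDH markers were higher on balance too. Of 15 integrins and adhesion genes, 7 were at least 2-fold higher and 3 lower, with a median of 0.97 (percentile 100). CEACAM6 (3.96), CEACAM5 (3.60) and ITGA5, the α subunit of the fibronectin receptor (3.58), were higher, and L1CAM was lower (−2.93). Of 12 stem-like and ALDH markers, 8 were measured, with 4 higher and 0 lower: KLF4 (3.46), SOX2 (3.28), ITGA6 (2.37) and SOX9 (2.24). The other 4 were within 2-fold: CD24 (0.74), ALDH1A3 (−0.22), BMI1 (−0.31) and CD44 (−0.57). ALDH1A1, PROM1, NANOG and LGR5 were under 1 FPKM in both libraries. Those 4 and the unmeasured ones were named after their values were seen. SOX2 stood at 0.0082 FPKM in P and 8.81 FPKM in TamR. The stem-like median was 1.49 (percentile 100), and 0.076 (percentile 94.9) without the filter on low values. Of 11 Notch pathway genes, 5 were higher and 1 lower, with a median of 0.99 (percentile 99.99). The ligand gene JAG1 (2.67) and the target genes HEY1 (4.73) and HES1 (1.75) were higher, and the receptor gene NOTCH1 was lower (−1.99). The target genes HES4 (0.80) and NRARP (−0.95) were within 2-fold, and HEY2 and HEYL were under 1 FPKM in both libraries. These last were named after their values were seen, as were HES4 and NRARP. Of 6 retinoic acid and androgen response genes, 1 was higher and 2 lower, with a median of −0.62 (percentile 3.18). CRABP2, a retinoic acid carrier, went from 498 to 30.5 FPKM (−3.98), DHRS3 was higher (3.01) and FKBP5 lower (−1.17), and CYP26B1 was within 2-fold (−0.82). With a pseudocount of 0.1 FPKM this median was −1.02 (percentile 0.85).

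**Figure D2:**
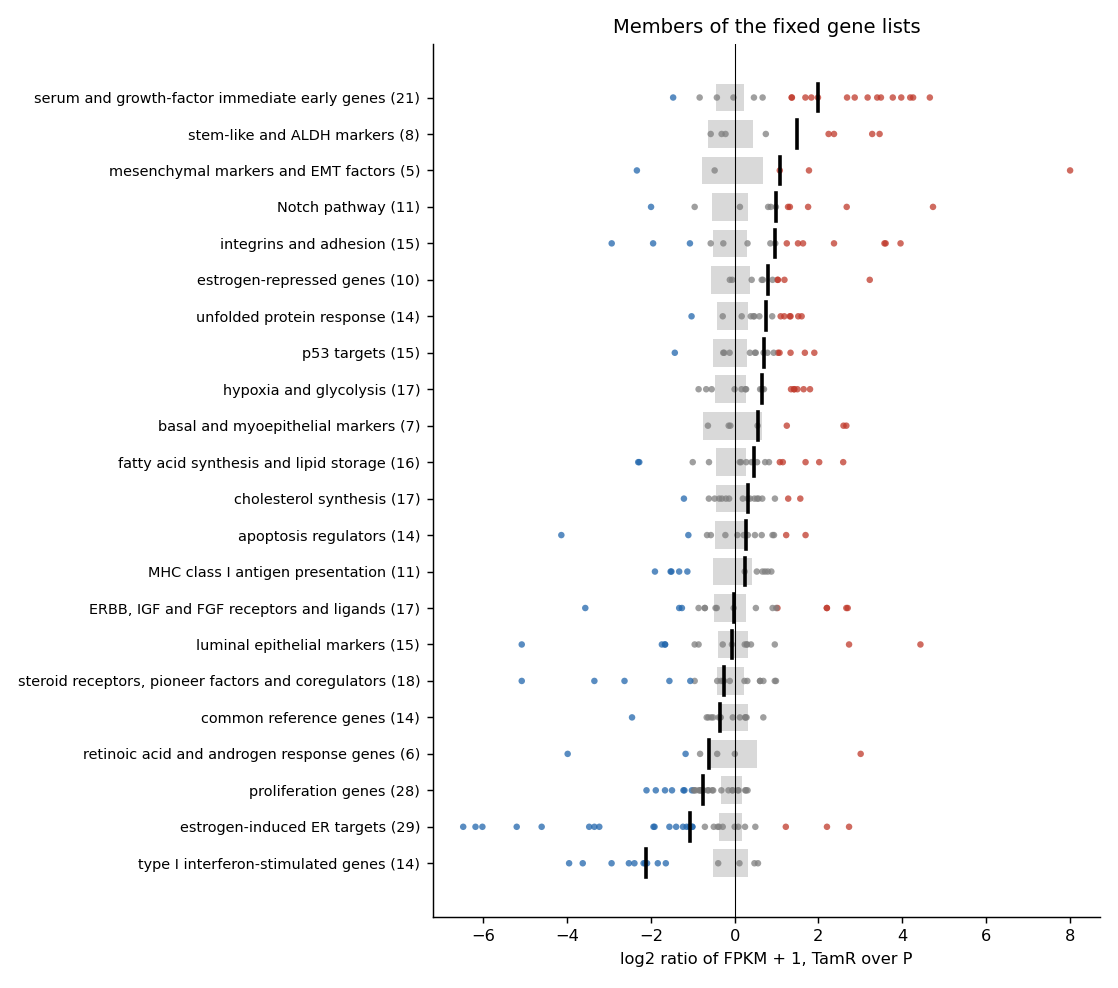
Each point is a list member's log2 ratio of FPKM + 1, TamR over P, for the fixed lists with at least 5 measured members (numbers in brackets). The black bar is the list's median and the grey band the central range of 10000 random lists. Red and blue points are at least 2-fold higher and lower. The immediate early and ERK feedback genes (median 1.99) and interferon-stimulated genes (median −2.11) lie at the ends.

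Most markers of other cell types were under 1 FPKM in both libraries. Of 12 leukocyte markers only CD68 reached 1 FPKM (1.42 in P and 1.65 in TamR), and of 8 endothelial markers only ERG (0.93 and 1.05 FPKM). Of 10 fibroblast markers only COL3A1, from 0.19 to 66.2 FPKM, and COL1A1, from 5.35 to 11.1 FPKM, reached 1 FPKM. Of 9 hepatic and neuroendocrine markers, 3 were measured. APOA1 (−3.40) and ENO2 (−2.69) were lower in TamR, and CHGA, at 1.01 and 0.0038 FPKM, was within 2-fold on the log2(FPKM + 1) scale.

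Among 14 common reference genes, 1 was at least 2-fold lower and 0 higher, with a median of −0.34 (percentile 5.01). HPRT1 went from 44.9 to 7.41 FPKM (−2.45). GAPDH was at 0.68, HMBS at −0.67 and RPLP0 at −0.63. Several of these genes lie among neighbours with ratios of the same sign, which was examined after the data were seen. Over windows of 41 expressed genes in chromosome order, the highest median, on chromosome 2 from FAM110C to SMC6, was 1.32 above that of all genes. All but 1 of its genes lay above the median of all genes, and the exception was GREB1. A window on chromosome 14 from NOVA1 to KLHL28, with FOXA1 in it, stood 1.08 above, with 41 of 41 genes above. The lowest window, on the X chromosome from XIAP to SPANXD, had a median of −1.31 relative to all genes and held XIAP, HPRT1 and SPANXA1. On the same relative scale, GAPDH and ENO2 lay in a higher window on chromosome 12 (0.78), LSS in one on chromosome 21 (0.71), and HMBS and APOA1 in a lower one on chromosome 11 (−0.62). HES1 lay in a lower window on chromosome 3 (−0.62). In 100 shuffled gene orders, window medians ranged from −0.53 to 0.61.

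**Figure D3:**
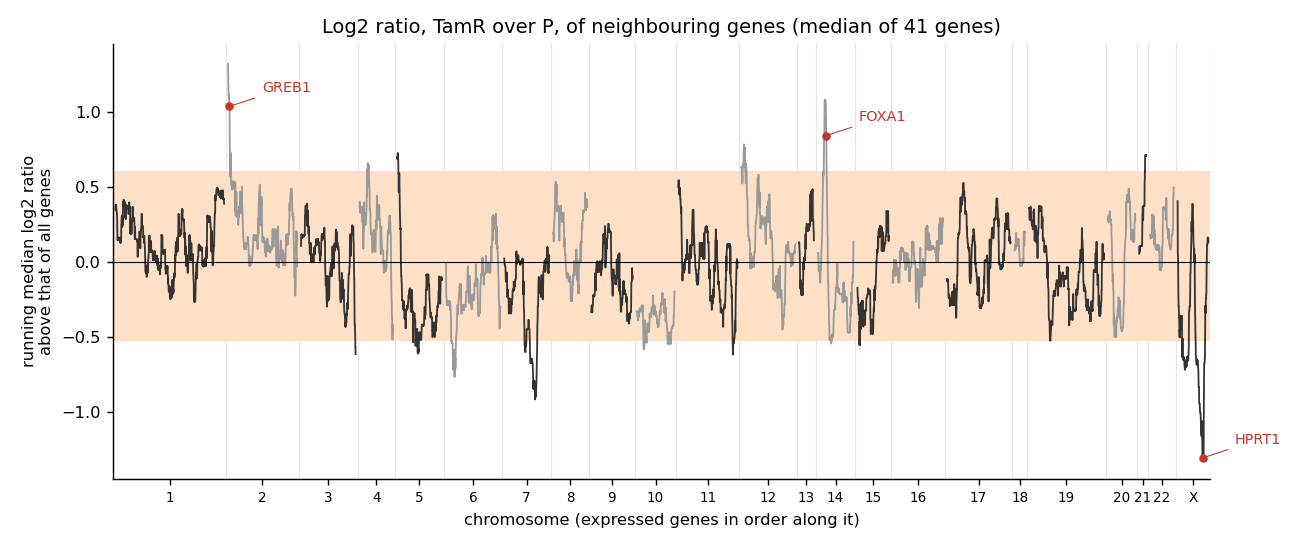
The line is the running median, over 41 neighbouring expressed genes, of the log2 ratio of TamR over P above that of all genes, with genes in order along each chromosome on the horizontal axis. The band spans the lowest (−0.53) and highest (0.61) window medians in 100 shuffled orders; FOXA1 and GREB1 lie in peaks above the band and HPRT1 in the lowest trough.

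The authors' deposited table lists 615 transcripts of 577 genes that met their threshold, with 309 transcripts higher in TamR and 306 lower. By its q-values, the leading higher transcripts in the authors' deposited table belonged to LDHB, HEY1, IL8, LOX and FADS2, each with a q-value of 0. LOX encodes a collagen cross-linking enzyme. The leading lower ones in the authors' deposited table were SPANXA1, SUSD3, CA12, GREB1 and IL20, also at 0. The authors' deposited table places the LDHB locus at chromosome 12, 21788275 to 21810776, and IL8 at chromosome 4, 74606274 to 74711916. It places GREB1, in the authors' deposited table, at chromosome 2, 11674241 to 11782912, all on hg19. In the authors' deposited table GATA3 had a log2 ratio of −3.91 (q = 7.54e-09) for one transcript and −3.99 (q = 0.00421) for another. PGR was at −3.03 (q = 1.10e-07) in the authors' deposited table. Of the fixed lists, the immediate early and ERK feedback genes had 10 members listed higher and 0 lower in the authors' deposited table. The estrogen-induced genes had 0 and 9 in the authors' deposited table, and the interferon-stimulated genes 0 and 5.

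Of the 615 transcripts in the authors' deposited table, 611 had the same direction in the FPKM table, and log2 ratios from both correlated across transcripts with a Pearson r of 0.975. The listed transcripts all had large ratios there between the same 2 cultures, so this agreement was largely fixed in advance. At gene level, 515 of its 577 genes were at least 2-fold different here in the same direction as in the authors' deposited table, 263 higher and 252 lower. This overlap was largely fixed in the same way. Of the 571 genes at least 4-fold different here, the authors' deposited table lists 330. FN1, EPAS1, COL3A1, RAB34, TFF3, AREG, SPRY4 and IFITM3 are not among the genes in the authors' deposited table. The FADS2 transcript had a log2 ratio of 3.90 in the authors' deposited table, while the total for the gene was 1.69 here. S100P reached 345 FPKM in TamR in the authors' deposited table and 1882 FPKM in the FPKM table. The gap grew with the level in the FPKM table. Values there over those in the authors' deposited table had a median ratio of 0.94 at 1 to 10 FPKM. It was 1.13 at 10 to 50 FPKM and 1.65 at 50 FPKM or more. Of 22 transcripts that the authors' deposited table lists at 0 in one library, 7 had 1 FPKM or more in that library in the FPKM table.

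**Figure D4:**
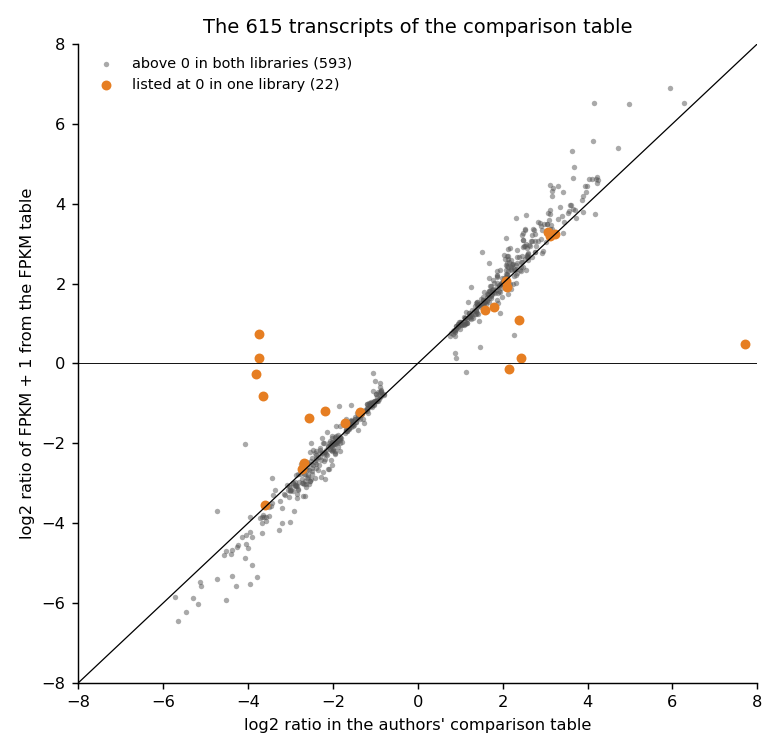
Each point is one of the 615 transcripts of the authors' deposited table, with its log2 ratio there on the horizontal axis and its log2 ratio of FPKM + 1 from the FPKM table on the vertical axis. Most lie near the line of equal ratios (Pearson r 0.975), which the large ratios of the listed transcripts largely fixed in advance. The 22 orange points are listed at 0 in one library, and 7 of these lie within 2-fold on the vertical axis.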

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

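The gene level from the most abundant transcript and the lists without the genes of the most extreme windows were tests chosen after the data were seen. All other settings were set before. A fixed number of separate windows was removed in each direction, so others beyond the shuffled range may remain. The counts higher and lower in TamR were 530 and 474 with a pseudocount of 5 FPKM, 2172 and 3018 at 1.5-fold, and 308 and 263 at 4-fold. They stayed within 1.5 times of 1152 and 1248 in the other 7 settings. Higher genes made up 48.0% of the 2-fold calls, and 55.7% with median-centred ratios. The overlap of 515 genes with the authors' list was 313 with a filter at 5 FPKM and 330 at 4-fold. The correlation of 0.884 was 0.825 with a pseudocount of 0.1 FPKM, 0.946 without a filter and 0.817 with a filter at 5 FPKM. Of 22 lists, 14 stood apart, and 12 of these did so in the same direction in every setting run. Without a filter the mesenchymal median turned from 1.08 to −0.0075, the stem-like median went from 1.49 to 0.076 and the retinoic acid and androgen median from −0.62 to 0.0018, where members near 0 FPKM entered. Medians that newly stood apart were those of the ERBB, IGF and FGF genes at 5 FPKM (0.49), the basal markers with a pseudocount of 0.1 FPKM (1.15), and the apoptosis regulators without the windows (0.32). The retinoic acid and androgen median did so with a pseudocount of 0.1 FPKM (−1.02), with equal totals (−0.82) and with the most abundant transcript (−0.97). The cause was not tested. With a filter at 5 FPKM the basal, mesenchymal and retinoic acid lists had under 5 members and gave no value. Of 119 named genes, none with a 2-fold ratio changed direction in any setting run, but 16 came within 2-fold with a pseudocount of 5 FPKM. Named genes within 2-fold passed it in 23 cases over all settings. Depth is unknown, so its limit on genes near 1 FPKM could not be given.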

Other observations

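The gene families below were chosen after the data were seen, as were the tests on fibroblast genes and all those of the third pattern. Of 16 families with at least 5 measured genes, 6 had a median outside the central range of random lists and 10 did not. Histone genes, taken as symbols that start with HIST and a digit, were lower in TamR as a family. Of 59, 18 were at least 2-fold lower and 0 higher (median −0.72, percentile 0 of 10000 random lists). Within this family the difference lay in the cluster on chromosome 6. Its 46 HIST1 genes had a median of −0.90, and the family's 13 other genes one of 0.18. Both directions held under 3 other scalings. The 10 genes of other families within the cluster had a median of −0.49, and the 20 nearest outside it one of −0.43. Histone genes under other symbols were left out of the family. Of these, H2AFX, named after its value was seen, was at −1.25 and lies in the lower window on chromosome 11. Histone genes have near-identical copies and mostly lack poly(A) tails, so single values are uncertain. Cytosolic ribosomal protein genes were lower by a small amount (82 genes, median −0.36, percentile 0), and the direction held under the same scalings.

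Of 8 claudins, tight junction genes, 3 were at least 2-fold lower and 0 higher (median −0.79, percentile 0.64), with CLDN3 at −2.42. CLDN1 and CLDN15 lie in the lower windows on chromosomes 3 and 7 (−0.62 and −0.92 relative to all genes). Collagens had a median of 0.93 (13 genes, percentile 99.98), with COL18A1 at 1.82 and COL6A2 at 1.56 but COL9A3 at −2.33 and COL12A1 at −2.23. COL18A1, COL6A1 and COL6A2 lie in the higher window on chromosome 21 (0.71 above all genes). Of 6 aldo-keto reductases, which reduce steroids and carbonyls, 4 were higher (median 1.16, percentile 99.8). AKR1C2 was at 2.62 and AKR1B10 at 1.78, though the AKR1C genes are close copies. The 328 zinc finger genes, with a median of −0.23, lay just outside the range (percentile 2.47), with 12 at least 2-fold higher and 16 lower. Families inside that range still held single genes with large ratios. In the HOXC cluster (percentile 53.9) HOXC10 went from 42.3 to 1.7 FPKM and its neighbour HOXC9 had a log2 ratio of 2.54. Among keratins (percentile 41.7), KRT8 and KRT18, partners in luminal keratin filaments, were both at −1.66, and both have many pseudogenes.

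The first pattern was genes nearly absent from P and abundant in TamR, such as FN1, COL3A1 and LOX (0.069 and 19.7 FPKM). Fibroblasts mixed into the TamR culture would bring their other abundant transcripts. The median of COL1A2, DCN, LUM, VIM and SPARC was 0% of the COL3A1 level, with VIM the highest at 5.69%, which argues against that source. The weight of this is limited, since these genes were chosen after the data were seen. COL1A2, DCN and LUM stood at exactly 0 FPKM, which can be a failed estimate. Another cell line in place of, or mixed into, the TamR culture may show through MTAP and CDKN2A, which MCF-7 lacks, but the higher of both, MTAP, was at 1.09 FPKM in TamR, between the bounds set in advance, and at 3.11 FPKM in P itself, so this remains open. A difference that comes with resistance, or with medium and drug, is the biological explanation in the design and was not tested.

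The second pattern was neighbouring genes, FOXA1 among them, with log2 ratios shifted in the same direction. Across 11273 genes in order, a gene's log2 ratio correlated with the mean of its neighbours 3 to 10 places away (r = 0.233, against at most 0.047 in 1000 shuffled orders). The correlation was 0.195 at 11 to 30 places (at most 0.042 shuffled). This argues against close neighbours counted with each other's reads, or in one short gene cluster, as the whole source. It cannot exclude families in longer clusters, such as the 46 HIST1 genes, which reach past 10 places. The 20 nearest neighbours of FOXA1 were 0.91 above all genes at the median, with 20 of 20 above but of unequal size (interquartile range 0.36 to 1.34). Segmental copy number differences, a gain around FOXA1 among them, and regulation over whole domains, with or without resistance, stay open, since DNA was not analysed here and 0.233 and 0.91 measure the pattern itself.

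The third pattern was calls in the authors' deposited table not met by the gene totals, 62 of 615 transcripts. Of these, 24 came from genes under 1 FPKM in total in both libraries, which cannot reach 2-fold with 1 FPKM added. By their own ratios in the FPKM table, also with 1 FPKM added, 47 of the 62 were under 2-fold. Some kept genes stopped just short of 2-fold, such as ZNF93 (0.99) and SEMA3E (0.99). The added 1 FPKM can therefore matter for more than those 24. Reads moved between transcripts of the same gene stay open. The other transcripts of the gene, where they summed to 1 FPKM or more, went the opposite way in 13 of 19 cases (68.4%, 95% exact interval 43.4% to 87.4%), which the choice of these genes largely fixes, and another transcript was at least 2-fold the opposite way in 4 of 62 (95% exact interval 1.8% to 15.7%), a count held down where levels are low. A candidate explanation for some others is a failed estimate written as 0 in the authors' deposited table, since 31.8% of the 22 transcripts listed at 0 there had 1 FPKM or more in the FPKM table, 6 of them among the 62. No biological explanation was tested for this pattern.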
